A study of Pseudomonas protegens with 6 samples.

How the data were processed

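RNA of the Pseudomonas strain NLX-4, listed under the species Pseudomonas protegens, was sequenced from 3 libraries of cultures given silicate rock as the potassium source and 3 libraries of control cultures given KCl. Per the labels' protocols, RNA was extracted with Trizol and ribosomal RNA was removed with a kit. The libraries kept the strand of the transcript, through dUTP in the second cDNA strand and its removal with UNG, and were read on a HiSeq2000. The aligner, the read counter and their settings, including whether counting used the strand, are not given in the sources used here. edgeR and limma are named in the submitters' processing notes, with no role and no version.

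The deposited values were RPKM (reads per kilobase of gene, scaled to the total of reads in the library), per the file headers, with 1 file for each library. Genes without a read are not listed in a library's file and were set to 0. Gene positions came from the deposited annotation, which per its source column was made with Glimmer, a gene finder for bacterial genomes, on 1 contig. It lists 6239 genes on 6.77 Mb, and gene, transcript and coding lines share their bounds. All 6239 lengths are multiples of 3, so length here means coding length. The deposited files do not pair gene IDs with names or products, and no reference annotation was used here. The gene lists fixed beforehand, among them potassium uptake, glucose oxidation, siderophores, exopolysaccharide and flagellum, therefore could not be used, and no function is given for any gene.

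RPKM multiplied by gene length gave whole multiples of 1 step per library. Of 36482 values, 100% came out within 0.001 of a whole number of reads. The totals on genes were 10642255, 5968251 and 4616782 reads for rock replicates 1, 2 and 3, and 9883855, 8323882 and 8970619 for control replicates 1, 2 and 3. A single read in a gene of 1 kb was worth 0.0940 RPKM in the deepest library and 0.217 RPKM in the shallowest. Intervals were not drawn from reads, since PCR copies are not independent molecules.

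The design, tests, gene lists and most other settings were chosen before the data were examined, with a count-based test planned for the case that counts were deposited. As the values were RPKM, the test planned for that case was used: limma with an intensity trend and robust variance on log2(RPKM + 1), for genes with at least 1 RPKM in 3 or more libraries. This kept 6018 genes. The pseudocount of 1 makes the fold changes of low genes smaller than the ratio of their RPKM values. Group was the only term of the model, p-values were adjusted by the Benjamini-Hochberg method, and a gene was said to have risen or fallen in rock at an adjusted p under 0.05. The labels do not say whether the 3 replicates of a group were separate cultures, so p-values measure the spread between these libraries, which may be technical. That spread is not each gene's own alone, since limma draws the variance of a gene toward a trend shared by all genes. With 3 libraries per group, very small p-values rest largely on this sharing.

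A run was a series of at least 5 consecutive tested genes, in the order of the annotation and on 1 strand, that passed the test in the same direction. Its number and longest length were set against 1000 permutations of the calls over gene places. The change of a run is the mean log2 fold change of its genes, and its p is from fry in limma, adjusted over the runs by the Benjamini-Hochberg method unless called unadjusted. The genes of a run were selected by their own calls, so that p is not independent evidence. Correlations across genes used 100000 permutations, and genes are not independent replicates. Group differences in library measures used a two-sided exact permutation test, adjusted over 6 measures. Principal components and Spearman correlations between libraries used log2 RPM (reads scaled to the total, without gene length) with a prior count of 2.

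The genes printed by ID followed a rule. They had to pass the test with a fold of at least 2, have at least 10 RPM on average, and have groups that did not overlap in any replicate. Of these, the 2 with the largest rise and the 2 with the largest fall were printed. The 10 longest runs were described by position, with ties broken by the size of their mean change. Coordinates are 1-based on the strain's own contig. In the annotation 1783 genes overlap another gene and 350 overlap a gene on the opposite strand. Without a stated strand setting, the reads of those pairs cannot be assigned with certainty. None of the 4 genes printed by ID overlaps another gene.

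The gene test was tested on simulated data for the comparison of rock with control, with 3 libraries per group and 200 of 6007 genes changed. It recovered 3.03% of the genes changed 2-fold, 65.2% of those changed 4-fold and 92.4% of those changed 8-fold. Of 111 genes called, 5 were false (4.50%), and 0 had the wrong direction. The simulated genes were drawn independently, with the same spread in both groups and with rises and falls equally likely. The spread of the most variable genes was capped, and no simulated library was placed between the groups. In the data 1666 of 6018 tested genes passed and the median gene was shifted, so these shares need not hold there. Other settings fixed beforehand covered the pseudocount, the filter, the scaling, limma-voom on the recovered reads, the very abundant genes, each library left out and the replicate number as a block. Median-of-ratios scaling, removal of a gene length trend with and without keeping each library's mean, thinning to the smallest library, a test against a fold of 1.5 and ordering genes by start were added after seeing the data. The software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with matplotlib 3.10.9 for the figures.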

Results

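Gene expression was measured in Pseudomonas strain NLX-4, a bacterium studied for its ability to dissolve rock, with potassium supplied in 2 forms. In the rock group, 5.0 g per litre of silicate rock was the sole potassium source, at 30 °C and 180 rpm for 15 days. The control group received 0.3 g per litre of KCl, a soluble potassium salt, and its label gives no culture time, temperature or shaking. Differences between the groups may therefore include these conditions as well as the potassium source. Each group had 3 libraries. Between 4616782 and 10642255 reads fell on genes per library, and between 5988 and 6113 of the 6239 annotated genes had a read. The series asks how the strain dissolves rock, and the comparison possible here is which genes and chromosomal regions differed between the groups.

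The libraries of the control group resembled each other more than those of the rock group did. The mean Spearman correlation across genes was 0.982 within the control group (3 pairs, 0.973 to 0.988) and 0.952 within the rock group (3 pairs, 0.946 to 0.956). It was 0.924 between groups (9 pairs, 0.883 to 0.972). Rock replicate 1 stood between the groups: its highest correlation was with control replicate 2, at 0.972, and it was 0.957 with control replicate 1, against 0.955 with rock replicate 2 and 0.946 with rock replicate 3. On the first principal component, which held 66.3% of the variance, it lay at 0.42 of the way from the control mean to the mean of rock replicates 2 and 3. As a check for a library deposited more than once, reads were compared between libraries of a group. Chi-square per degree of freedom, which allows for counting error only, was at least 70.8, so no pair was a copy.

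**Figure D1:**
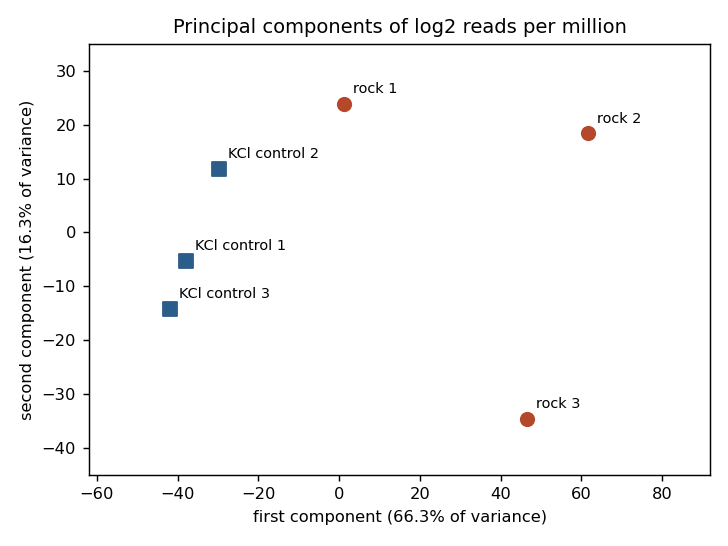
Principal components of log2 RPM over the tested genes, with 1 point per library (circles, rock; squares, KCl control). The first component (66.3% of the variance) has the 3 controls at one end, rock replicates 2 and 3 at the other and rock replicate 1 between them, and the second (16.3%) parts rock replicate 3 from the others.

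Reads were more concentrated on abundant genes in each rock library than in any control library, although 3 libraries against 3 cannot pass a threshold of 0.05. The 10 most abundant genes of each library took 18.8% ± 2.07 of reads in rock and 15.0% ± 1.49 in control (SD, n = 3; exact permutation p = 0.1, adjusted p = 0.2). The 312 most abundant genes, 5% of the annotation, took 63.4% ± 3.41 in rock and 57.1% ± 1.06 in control (SD, n = 3; exact permutation p = 0.1, adjusted p = 0.2). The p of 0.1 is the smallest that this design can give. The total of reads was 7075763 ± 3161727 in rock and 9059452 ± 783771 in control (SD, n = 3; exact permutation p = 0.4).

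Among genes with at least 10 RPM on average and groups that did not overlap, NZ1GL005331 had the largest rise with a pseudocount of 1, at 5770975 to 5772450 on the plus strand. It went from 3.99 ± 2.19 RPKM in control to 67.3 ± 30.7 RPKM in rock (SD, n = 3), a ratio of means of 16.9. Its log2 fold change was 3.75 (SE 0.41, limma adjusted p = 2.29e-08), on 35 to 859 reads per library. NZ1GL004500, at 4880707 to 4881474 on the minus strand, was among the most abundant genes of the rock libraries. It rose from 3598 ± 191 to 39225 ± 16157 RPKM (SD, n = 3), with a log2 fold change of 3.35 (SE 0.48, limma adjusted p = 4.86e-06). With a pseudocount of 5 the order of the pair turned, at 2.94 for NZ1GL005331 and 3.35 for NZ1GL004500. With median-of-ratios scaling their log2 fold changes were larger, at 4.17 and 3.83, but the limma adjusted p-values were 0.00533 and 0.0109.

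By the same selection, NZ1GL003455 and NZ1GL004030 had the largest falls, and their order turned when rock replicate 1, rock replicate 2 or control replicate 3 was left out. NZ1GL003455, at 3778847 to 3779413 on the plus strand, fell from 4085 ± 1667 RPKM in control to 489 ± 454 RPKM in rock (SD, n = 3). Its log2 fold change was -3.41 (SE 0.59, limma adjusted p = 0.00120). NZ1GL004030, at 4387087 to 4388709 on the plus strand, fell from 623 ± 267 to 64.9 ± 33.4 RPKM (SD, n = 3), with a log2 fold change of -3.29 (SE 0.40, limma adjusted p = 2.66e-07). All 4 genes passed the test in the same direction under each alternative that was run for them.

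Across the genome, 1666 of 6018 tested genes (27.7%) differed between rock and control cultures at a limma adjusted p under 0.05. Of these, 474 rose in rock and 1192 fell, and 454 and 1089 of them changed at least 2-fold. The groups did not overlap in 1550 of the 1666 genes, and in 45.0% of all tested genes, where chance gives 10% for a single gene. All genes share the same 6 libraries, so setting 45.0% against 10% is not a test. Overlap was scored on RPKM only, where a shift of the median gene can add to the share. The split between rise and fall depended on scaling, because the median tested gene had a log2 fold change of -0.46 under RPKM scaling. With median-of-ratios scaling, which brought that median to -0.02, 881 genes passed, of which 632 rose and 249 fell. Of the genes called under both scalings, 443 rose and 248 fell, and 0 changed direction, which was unlikely from the start because scaling moves all genes alike. The share of calls that rose was thus 28.5% under one scaling and 71.7% under the other.

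The number of genes past the test depended on single libraries. It was 154 without rock replicate 2, 2928 without rock replicate 1, 599 without control replicate 1 and 715 without control replicate 3. A core of 144 genes passed with all 6 libraries and with any 1 of them left out, of which 59 rose and 85 fell.

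**Figure D2:**
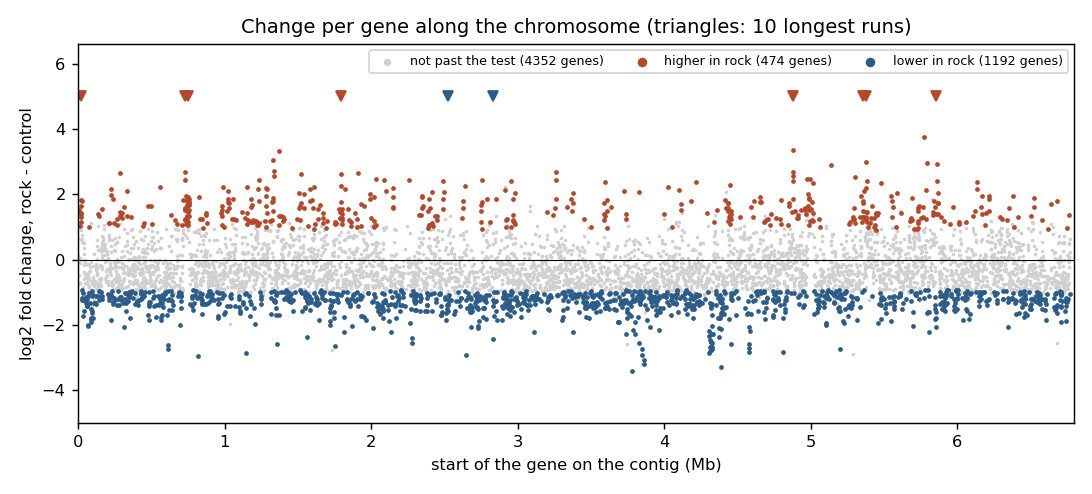
Log2 fold change (rock minus control, RPKM scaling) of each of the 6018 tested genes against its start on the contig in Mb, with 1 point per gene (red, 474 genes higher in rock; blue, 1192 lower; grey, not past the test). Triangles mark the 10 longest runs of neighbouring genes, 8 higher and 2 lower. Between 3.39 and 4.4 Mb 28.6% of the genes fell, against 19.8% of all tested genes.

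Some genes that rose lay together on the chromosome, while 251 of the 474 had no adjacent tested gene that rose on the same strand. The longest run held 10 consecutive genes on the plus strand from 726579 to 741340, with a mean log2 fold change of 1.66 and gene values from 1.10 to 2.68. The mean of its log2(RPKM + 1) values was 10.05 ± 0.50 in rock and 8.39 ± 0.26 in control (SD, n = 3; limma fry adjusted p = 0.0236 over 22 runs). A second run of 9 genes, from 745503 to 748988 on the same strand, rose by a mean of 1.69 (limma fry adjusted p = 0.0236). These runs and 2 runs of 5 genes lay within 29.826 kb, from 726579 to 756404. In that window, delimited after its values were seen, 33 of 38 tested genes rose and 0 fell, and 34 rose with median-of-ratios scaling.

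The strongest mean change of a run was at 4877887 to 4881474 on the minus strand, where 5 genes, NZ1GL004500 among them, rose by a mean log2 of 2.57. Their mean log2 value was 12.93 ± 0.63 in rock and 10.35 ± 0.10 in control (SD, n = 3; limma fry adjusted p = 0.0236). The 6 genes from 5379010 to 5384821 on the minus strand rose by a mean of 1.90, and the 6 from 5353991 to 5362458 on the plus strand by 1.61. The unadjusted fry p of the latter was 0.0142, and 0.0505 to 0.0520 without rock replicate 3, control replicate 1 or control replicate 3. On the plus strand, 6 genes from 16749 to 21964 rose by 1.46 and 6 from 1796242 to 1801257 by 1.34. The last were abundant in both groups, with a mean log2 value of 11.38 ± 0.36 in rock and 10.04 ± 0.28 in control (SD, n = 3).

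A run of 7 genes from 5858248 to 5874195 on the plus strand had a mean log2 fold change of 1.95. Its rock libraries were far apart, at 5.73, 7.28 and 7.53 for replicates 1, 2 and 3, against 4.90 ± 0.09 in control (SD, n = 3). Its unadjusted fry p of 0.0251 rose to between 0.0697 and 0.0797 when any 1 library other than rock replicate 1 was left out.

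Runs of genes that fell were shorter, and the calls of their single genes depended on scaling. The 6 genes from 2831306 to 2838661 on the plus strand fell by a mean of 1.52 on the log2 scale, from 4.39 ± 0.15 to 2.87 ± 0.43 (SD, n = 3; limma fry adjusted p = 0.0236). The 6 genes from 2525736 to 2532493 on the plus strand had a mean log2 fold change of -1.26 (limma fry adjusted p = 0.0288). Its unadjusted fry p of 0.0228 rose to between 0.0627 and 0.0728 without rock replicate 3, control replicate 1 or control replicate 3. With median-of-ratios scaling the means were -1.10 and -0.80, and 1 of the 6 genes in each run still passed the gene test, while the unadjusted fry p of the runs was 0.00678 and 0.0286.

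In all, 22 runs of at least 5 genes were found, 11 higher and 11 lower in rock, with 127 genes. Permuted calls gave 0.416 runs on average and 6 at most (one-sided permutation p = 0.001, the smallest that 1000 permutations can give). Such permutations ignore that neighbouring genes often share a transcript, so a small p was likely from the start. It shows only that calls lay together more than in random order. With median-of-ratios scaling 14 runs were found, all of genes that rose (one-sided permutation p = 0.001), and each gene of the 11 rising runs still passed. Without rock replicate 2 there were 0 runs and without rock replicate 1 there were 54. The count was 14 without rock replicate 3, 6 without control replicate 1 and 9 without control replicate 3.

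**Figure D3:**
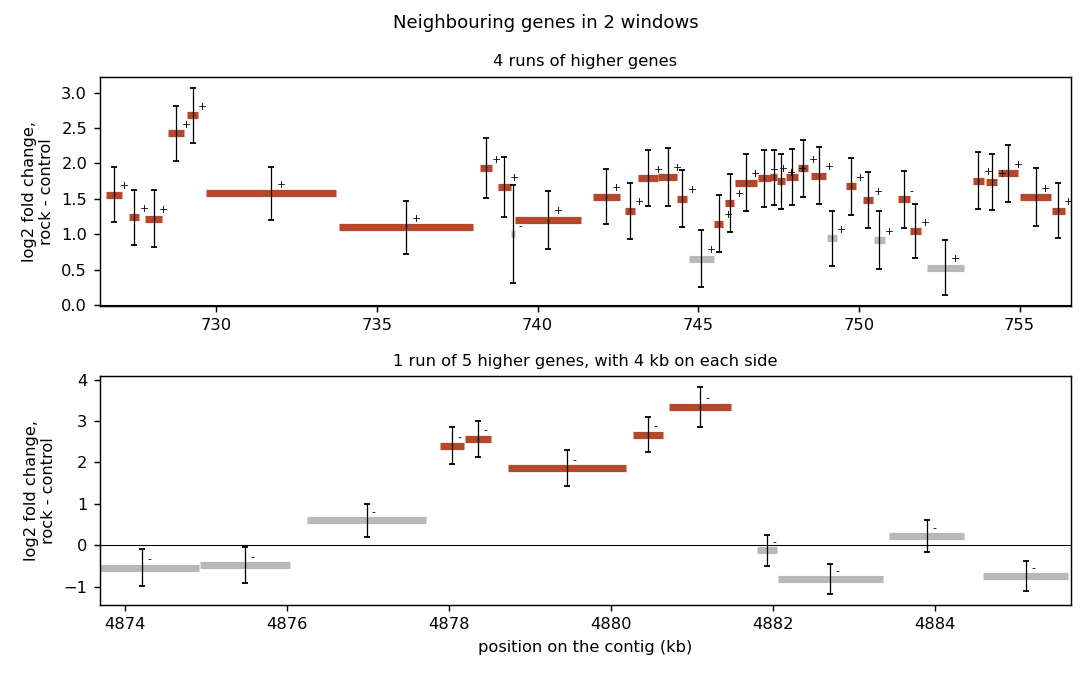
Log2 fold change (rock minus control) of neighbouring tested genes against position in kb, with each gene drawn as a bar over its length, its standard error as a vertical line and its strand as a sign (red, higher in rock; grey, not past the test). The upper panel shows a window that holds 4 runs with 29 genes, and 33 of all 38 tested genes in it rose. The lower panel shows 5 genes with a mean log2 fold change of 2.57 beside neighbours that did not pass.

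Short genes were higher in rock relative to long genes. Of 967 tested genes of up to 400 bp, 145 rose and 90 fell, with a median log2 fold change of 0.03. Of 2247 genes over 1000 bp, 111 rose and 533 fell, with a median of -0.59. With median-of-ratios scaling, 175 short genes rose and 14 fell, while 173 long genes rose and 125 fell. Across genes the rank correlation of change with length was -0.21 (permutation p = 1e-05, the smallest possible; Pearson r = -0.15; adjusted p = 3e-05 over 3 measures). Within the rock group, the log ratio of replicates 1 and 2 correlated with length as strongly, at 0.238. The correlation of change with mean level was 0.05 (permutation p = 4e-05, adjusted p = 6e-05), and its sign turned with a pseudocount of 5 and with quantile normalization. It was 0.0137 with limma-voom (permutation p = 0.304), 0.00748 without rock replicate 2 (permutation p = 0.563), and 0.197 among genes with at least 10 RPM in 3 libraries. That with position along the contig was -0.01 (permutation p = 0.261). Such a correlation sees only a steady trend. The share of genes that fell ranged from 12.1% to 29.2% over 20 equal parts of the contig. Both strands were alike: 233 of 2910 genes on the plus strand rose and 586 fell, and 241 of 3108 on the minus strand rose and 606 fell.

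**Figure D4:**
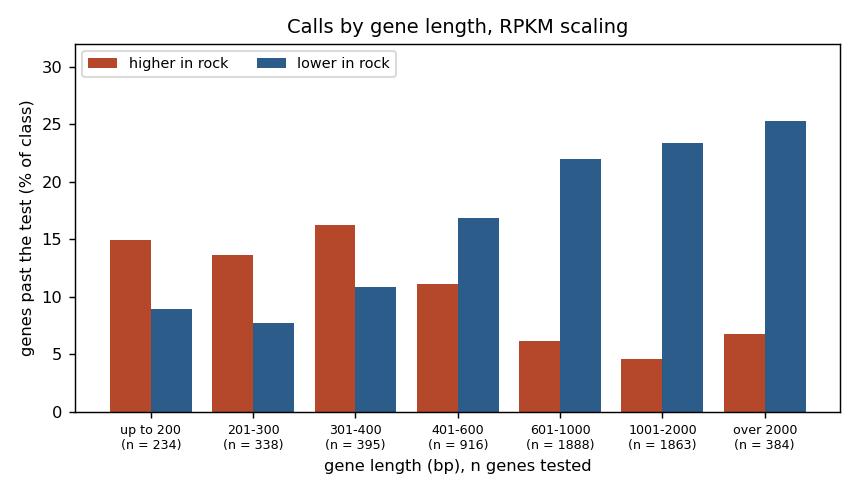
Share of tested genes past the test under RPKM scaling, in percent, by class of gene length in bp (red, higher in rock; blue, lower in rock; n is the number of genes in the class). Genes of up to 200 bp rose in 15.0% and fell in 8.97%, and genes over 2000 bp rose in 6.77% and fell in 25.3%.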

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

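Median-of-ratios scaling, removal of a gene length trend, the test against a fold of 1.5, thinning of reads and ordering genes by start were chosen after the data were seen; the other alternatives were planned. The number of genes that differed was 1666, with 474 higher and 1192 lower. Quantile normalization gave 1101 genes with 468 lower, upper-quartile scaling 1030 with 387 lower, median-of-ratios scaling 881 with 249 lower, and limma-voom with median-of-ratios scaling 974 with 272 lower. The share of calls that rose moved from 28.5% to 57.5%, 62.4%, 71.7% and 72.1% in these. Removing the length trend gave 991 genes, 428 lower, but also moved the median gene to -0.12; with library means kept it gave 1487, 1067 lower. In both the correlation with length was -0.00030, by construction. A limma test against a fold of 1.5 passed 160 genes, 81 higher and 79 lower, with 0 runs of 5 and a longest run of 3. For the other settings with all 6 libraries the number was between 1455 and 2097. In 0 of the alternatives did a gene called in both fits change direction. The fits share libraries, and scaling moves all genes by about the same amount. Such a change was therefore unlikely from the start, and its absence says little about stability.

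Leaving out 1 library gave 154 to 2928 genes, with 65 to 654 higher and 89 to 2274 lower, 0 to 54 runs and a longest run of 3 to 11 genes. The fewest were without rock replicate 2, and the most genes without rock replicate 1. Runs numbered 22, and 107 at 3 or more genes, 2 at 8 or more, 5 at an adjusted p of 0.01, 14 with median-of-ratios scaling and 21 with genes ordered by start. The longest run had 17 genes with at least 10 RPM in 3 libraries, where fewer genes were tested, and 9 with genes ordered by start. The mean correlation within rock was 0.946 by Pearson's r. The weak correlation of change with mean level reversed to -0.0584 with a pseudocount of 5 and to -0.0465 with quantile normalization; the cause was not tested. The 4 genes printed by ID passed in all of their 83 values, from 20 or 21 alternatives per gene. Of 200 values for the 10 runs described, 187 stayed under an unadjusted fry p of 0.05 and 13 did not, with 0 turned in sign.

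With the replicate number as a replicate block, 2097 genes passed, 597 higher and 1500 lower. The unadjusted fry p of the runs at 745503 to 748988 and 5858248 to 5874195 was 0.0513 and 0.0636 in that fit, and the other 8 runs described stayed under 0.05. Deviations of libraries with the same number correlated at 0.04, 0.25 and 0.21. Not every pair exceeded 0.1, so the libraries were taken to share only a number. Every library correlated best with its own number except control replicate 1, which correlated at 0.05 with rock replicate 3, a hint from the data and not from the design.

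Planned but not run were edgeR, DESeq2 and their size factors and fold test, which were set for deposited counts and were not applied to RPKM, the gene lists, which need names, and removal of stable RNA genes, which the annotation does not mark. Library size alone is the RPKM scaling itself. Depth limits low genes most.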

Other observations

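The tests of a wrong label, of mixed RNA, of the 10 most abundant genes and of blocks along the chromosome were chosen after their results or the pattern had been seen, as were the windows and the positions listed first. A further requirement, that the bounds for the most abundant genes hold with each library left out, was also added afterwards.

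Some very abundant genes differed strongly between libraries. The most abundant of all by mean RPKM, which unlike reads is scaled to gene length, was 180 bp at 4563908 to 4564087 on the plus strand. It had 58815 ± 26615 RPKM in rock and 34557 ± 7302 in control (SD, n = 3), with a limma adjusted p of 0.345. The gene at 4651739 to 4652716 on the minus strand rose from 8550 ± 827 to 32351 ± 15551 RPKM (SD, n = 3), with a log2 fold change of 1.77 (limma adjusted p = 0.00876, and 0.0396 with median-of-ratios scaling). The genes at 5733388 to 5733693 on the plus strand and 1632718 to 1632930 on the minus strand had log2 fold changes of 1.57 and 1.53 (limma adjusted p = 0.0224 and 0.0238). They had 38148 ± 24836 and 32579 ± 20201 RPKM in rock, and 10814 ± 1031 and 9481 ± 724 in control (SD, n = 3). Rock replicate 1 was close to the controls in both, at 13773 and 11537 RPKM. With median-of-ratios scaling the fold changes were larger, at 2.05 and 2.02, and the adjusted p-values were 0.0675 and 0.0699. The gene at 836001 to 837521 on the minus strand had 18774 ± 10497 RPKM in rock and 25481 ± 3491 in control (SD, n = 3; limma adjusted p = 0.380).

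Among genes of at least 1000 RPKM on average, 3 varied most between the controls, and they did so together. The gene at 4809091 to 4810680 on the minus strand had 14869, 11363 and 2578 RPKM in control replicates 1, 2 and 3. Its neighbour at 4810746 to 4811057 had 15053, 10768 and 3237 RPKM, and the gene at 1754139 to 1756055 on the plus strand had 8998, 5280 and 2002 RPKM. All 3 were lower in rock, with log2 fold changes of -2.84, -1.80 and -2.63 (limma adjusted p = 0.00411, 0.00648 and 0.000283). In rock replicates 1, 2 and 3 the first had 2248, 698 and 747 RPKM. The second had 2299, 1895 and 2843 RPKM, and the third 1120, 475 and 744 RPKM. Control replicate 3 was thus only slightly above the highest rock library in the first 2 genes.

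With 1666 genes past the test in the real grouping, the highest of the other splits of the 6 libraries gave 0, so 1 of 10 splits gave as many. That is the smallest share the design allows, and 10 splits are too few for a share under 0.05. Every other split has rock and control libraries on both sides, so any difference between the groups counts as spread there. The 0 was thus likely from the start and adds no evidence.

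Rock replicate 1 lay between the controls and the other rock libraries. A control culture under a wrong label would lie where a left-out control lies, but over genes selected without it, its lowest median position was 0.322 of the way to the other rock libraries. Left-out controls lay between -0.07 and 0.21, and rock replicate 1 was above the left-out control in each of 6 sets. This argues against a wrong label for the selected genes, with only 3 controls as reference. Across all tested genes, rock replicate 1 correlated with control replicate 2 at 0.972, close to the 0.973 between control replicates 2 and 3. A wrong label is therefore not ruled out. The number of reads alone does not account for the position of rock replicate 1 on the first component. With all libraries thinned to the smallest it was 0.415 at most, against 0.416 without thinning. Thinning changes read numbers only. Rock replicate 1 had 10642255 reads, against 5968251 and 4616782 in rock replicates 2 and 3 and 8323882 to 9883855 in the controls. A difference between libraries that goes with depth was not tested. A mixture of control and rock RNA may remain: it needs 1 share of control RNA from rising and falling genes, and the estimates differed by 0.392 at least, but the intervals overlapped with rock replicate 2 held out and not with replicate 3, so a mixture cannot be told apart from a culture that responded less.

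The median gene had a log2 fold change of -0.46 under RPKM scaling. Leaving out the 10 most abundant genes and rescaling left it at -0.42, and between -0.58 and -0.32 without any 1 library, so those genes alone do not account for it. Leaving out the 312 most abundant genes left it at -0.28, with -0.18 without rock replicate 2, so how far they could account for it stays open. A real fall of many transcripts and a rise of abundant ones give the same RPKM values without an outside standard.

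Short genes were higher relative to long ones in rock. Low read numbers alone are argued against, because the correlation of change with length was -0.224 (95% bootstrap interval -0.26 to -0.19) among the 3009 genes with the most reads. Short genes enter that set only at a higher RPKM, so length and level were not separated there. Differences between library preparations, such as fragment size, may account for it, since the log ratio of rock replicates 1 and 2 correlated with length at 0.238, as strongly as the groups did. Among pairs of controls the largest was 0.0393. Rock replicates also differ in how far they lie from the controls, so a response of short genes to rock remains open.

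A hypothesis was that neighbouring genes changed together because genes close by on 1 strand often share a transcript. Adjacent genes on 1 strand and 1 to 50 bp apart had a rank correlation of change of 0.63 (1056 pairs), against 0.31 for those over 200 bp apart (702 pairs) and 0.19 for adjacent genes on opposite strands (1777 pairs). The first exceeded the last by 0.439 (one-sided permutation p = 0.001, the smallest possible), which is consistent with shared transcripts. Opposite-strand neighbours were also farther apart, with a median of 134 bp, so distance and strand were not separated.

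The share of genes that fell differed along the chromosome. From 3.39 to 4.4 Mb, 245 of 857 genes fell and 26 rose, and from 0.68 to 2.03 Mb, 203 of 1266 fell and 164 rose. With median-of-ratios scaling the counts were 74 and 33 in the first window, and 32 and 205 in the second. A hypothesis that operon-sized neighbourhoods alone give this was tested by shuffling blocks of 10 genes. Of 1000 shuffles, 0% reached the chi-square of 106.9 over 20 parts of the contig, where the 95th percentile was 55.6 (one-sided permutation p = 0.001, the smallest possible). The cause of the unevenness at larger scale was not tested.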
